A study of Homo sapiens with 25 samples.

How the data were processed

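Chromatin immunoprecipitation with sequencing of H3K27ac, H3K27me3 and H3K4me2 was deposited for human H1 embryonic stem cells and 3 differentiated stages, definitive, anterior foregut and pharyngeal foregut endoderm. Of 25 samples, 21 have a peak list that was used, and the 4 input samples, 1 per stage, enter only as the authors' controls. Each of the 4 stages has 2 libraries per mark, except that H3K27me3 of hAFE and H3K4me2 of hAFE and hPFE have 1 each. Per the labels, the hESC H3K27ac and H3K27me3 libraries are re-analysed from an earlier deposit. Batch and stage therefore cannot be told apart in any contrast of these marks with hESC. The file names of 3 H3K27me3 libraries (replicate 1 of hESC, hDE and hPFE) carry the word millipore. The sources used here do not say whether it names another antibody, so the replicates of these stages may differ in antibody, and the single hAFE library does not carry the word. A stage count for H3K27me3 requires both libraries to agree, and leaving out replicate 1 moved gains from 127 to 721 in hDE and from 227 to 796 in hPFE, both against hESC. Leaving out replicate 2 of the same stage gave 218 and 689. With 1 library left out counts rise by construction, and in hPFE the rise was not particular to replicate 1.

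The authors called peaks per library against the input of its stage, on sorted alignments without duplicates, per the deposited file names, which also give a p-value threshold of 0.01 and a cap of 500 K peaks. No list reached that cap, and the lowest −log10 p was 2.00. The genome build is hg38 per the submitters' processing notes. The aligner, the peak caller and their versions are not given in the sources used here. Each peak in the deposited narrowPeak files has an integer score, a fold enrichment (a ratio of signal over control), a −log10 p and a −log10 q, all of them the authors' own values for that list. The deposited fold enrichment is printed to describe a peak, and the deposited −log10 p and −log10 q values rank or filter peaks within 1 list. No value was compared between lists. The fold enrichment printed for a gene is that of its strongest peak at a gene end, in replicate 1 and then replicate 2.

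Lists held 24871 to 111256 peaks over 9.60 to 46.0 Mb for H3K27ac, 23457 to 76441 peaks over 15.7 to 31.8 Mb for H3K27me3, and 87357 to 116210 peaks over 34.6 to 51.0 Mb for H3K4me2. Read counts were not used here, so the sequencing depth behind each list is unknown and a missing peak is not proof of a missing mark. The labels do not say whether replicates are separate cultures, so the permutation p-values measure only the spread between these samples. Fisher's exact tests count genes after the libraries are combined into calls, so their p-values do not measure any spread between libraries. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only. Genes that are neighbours can share a peak, so genes are not independent units in the list tests.

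Overlapping peaks of 1 library were merged and chromosomes 1 to 22, X and Y kept. The gene table (GRCh38.p14, 59679 genes, 20037 of them protein-coding) gives start and end but no strand, so the planned window around the transcription start was replaced, after the files were seen, by windows of 1 kb either side of both annotated ends. In each library 5.01 to 17.6% of the marked genes had peaks at both ends. A gene was marked at a stage if every library had at least 1 bp of a peak in its windows, and unmarked if none had. Gained and lost genes went from unmarked to marked or back. With 2 libraries per stage no p-value was computed for these counts. The counts of the 2 mixed splits, each with 1 library of either stage on each side, stand beside them. Contrasts in which a stage has 1 library are given as counts alone.

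Fixed lists, written before the data were examined, held 337 genes in 15 groups: pluripotency, primitive streak, definitive endoderm, anterior foregut and pharyngeal endoderm, thymus with parathyroid and thyroid, lung with oesophagus and stomach, liver with pancreas and intestine, neural, neural crest and mesenchyme, mesoderm with heart, blood and endothelium, epithelium, retinoic acid, signalling feedback (Nodal, BMP, WNT, FGF, Hedgehog and Notch), housekeeping and the HOX clusters. Some genes stand in more than 1 list, so calls for different lists can rest on the same genes. EOMES, GSC, MIXL1 and LHX1 are both primitive streak and definitive endoderm genes, LEFTY1 is a pluripotency, definitive endoderm and signalling feedback gene, CER1 and SP5 are also signalling feedback genes, HHEX, FGF8 and FOXA2 are also pharyngeal genes, MEIS1, MEIS2 and TSHZ1 are pharyngeal and retinoic acid genes, and HOXA2 and HOXB2 are pharyngeal and HOX genes. Two-sided Fisher's exact tests compared the share of a list's genes that changed with that of all other protein-coding genes that could have changed, with Benjamini-Hochberg adjustment over 270 tests and a threshold of 0.05 for the adjusted p. They gave 34 calls, 28 of a larger and 6 of a smaller share. Adjustment over the 15 lists of 1 contrast and direction alone is given where it made another call. Genes with a peak in some libraries of the later stage count as not changed, as planned. A version without those genes was seen first and is given as an alternative. Exchange of H3K27me3 and H3K27ac and the fate of bivalent genes were tested in the same way over 5 tests. Same-stage similarity was tested with one-sided exact permutation of the libraries over stages, adjusted over 3 marks.

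Distal regions were merged H3K27ac peaks more than 2 kb from any annotated gene end. Each was assigned to the nearest end of a protein-coding gene within 100 kb, and the lists were tested over genes with 150 tests. Overlap with H3K4me2 was compared with 100 random placements of the regions. Where the annotation places regions in genes, exon and intron positions were not used here.

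Genes named in the text follow a rule written before the data were examined. It takes the genes of the lists that changed in a contrast, up to 6 per list in order of mean rank by −log10 p, the 10 gained and 10 lost genes outside the lists with the best mean rank, and a few fixed genes, SOX17, FOXA2, PAX9, TBX1, PAX1, EYA1, HOXA3, POU5F1, NANOG and SOX2 among them, in every stage. Some genes that the rule takes are not reported here. Names outside the rule are said to be chosen after their values were seen. Of 473 gene calls under the rule, 169 were made under every setting tried and 0 turned direction. Absent were 173 over whole genes, 127 with a 2.5 kb window and 77 with peaks of −log10 p of 5 or more.

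Alternatives chosen before the data were examined were peaks of −log10 p of 5 or more, peaks of −log10 q of 2 or more, lists of equal length within a contrast, windows of 500 bp and 2.5 kb, an overlap of 200 bp, a peak in any library, replicate 2 alone for H3K27me3, marked gene sets and a replicate block for similarity, a limit of 50 kb for distal regions, 25% coverage or replicate 1 alone for H3K4me2 at distal regions, and each library left out in turn. Chosen after the data were seen were the gene end with more H3K4me2, the whole gene with 1 kb either side, the background without genes marked in some libraries, and, for distal counts and lists, equal lengths of the counts and each library left out. Consensus words and a background matched on CpG content were planned and not run, since no genome sequence was at hand.

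The procedures were tested on simulated data with planted changes. Overlaps were wrong in 0 of 4000 windows against a count base by base. Changes were planted on the hESC H3K27ac states, with error rates derived from the hESC and hPFE H3K27ac replicates but set too high. The rate of missed peaks pooled the differing genes of both stages, and that of extra peaks was not split between the libraries of a pair. Errors in this simulation are therefore more frequent than between the real replicates. Of planted changes at 20037 genes, 68.5% of the gains and 61.5% of the losses were called, out of 200 planted each way, and 155 gains and 183 losses were called where none was planted. Among random lists 1.4% had p under 0.05. The similarity test gave p under 0.05 in 3.5% of 200 sets without and 100% of 50 sets with a stage effect. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.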

Results

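The cells were H1, an established human embryonic stem cell line (hESC), and its derivatives after directed differentiation to definitive endoderm (hDE), anterior foregut endoderm (hAFE) and pharyngeal foregut endoderm (hPFE). Pharyngeal endoderm is the layer from which the thymus, parathyroid and thyroid arise. H3K27ac marks active promoters and enhancers, H3K27me3 marks genes held silent by Polycomb, and H3K4me2 marks promoters and enhancers that are active or accessible. The question addressed was which genes and distal regions carried each mark at each stage, and how the marks changed from 1 stage to the next. A gene counted as marked at a stage when every library of that stage had a peak within 1 kb of either annotated gene end, as unmarked when none had, and as gained or lost when it went from unmarked to marked or the reverse.

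H3K27ac covered the gene ends of broadly used genes at every stage, and H3K27me3 those of developmental regulators. Of the 24 housekeeping genes of a fixed list, 22 carried H3K27ac in hESC, 23 in hDE, 18 in hAFE and 23 in hPFE, and 1, 0, 1 and 0 carried H3K27me3. H3K27me3 lay on 26, 26, 25 and 26 of the 26 neural regulators and on 39, 39, 39 and 35 of the 39 HOX genes in hESC, hDE, hAFE and hPFE. Among 20037 protein-coding genes, 8592 carried H3K27ac in hESC, 10824 in hDE, 6860 in hAFE and 10063 in hPFE. H3K27me3 was found at 3850, 2692, 3101 and 2551 genes, where hAFE has 1 library. H3K4me2 was broader, with 14489, 13634, 14071 and 14053 genes, of which the last pair of stages rest on 1 library each.

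On average libraries of one stage shared more peak area than libraries of different stages for each mark. The mean Jaccard index (shared over combined bp) was 0.348 within and 0.167 between stages for H3K27ac, a difference of 0.181 that was the largest among all 105 partitions of the 8 libraries (one-sided exact permutation p = 0.00952, adjusted p = 0.0222 over 3 marks). For H3K27me3 the indices were 0.427 and 0.313 over 7 libraries (2 of 105 partitions as large, exact p = 0.0190, adjusted p = 0.0222). For H3K4me2 they were 0.463 and 0.316 over 6 libraries (1 of 45 partitions, exact p = 0.0222, adjusted p = 0.0222). The hPFE H3K27me3 pair was an exception with an index of 0.303, below that of hPFE replicate 2 with the hAFE library (0.367) and below the highest between stages (0.409, hESC and hDE replicates 1). Among H3K27ac libraries the hPFE pair (0.256) and the hESC pair (0.280) lay below hAFE replicate 1 with hPFE replicate 1 (0.315). Without 1 library the H3K27me3 call ended in 4 cases: the exact adjusted p was 0.0667 without hESC replicate 1 or either hDE replicate and 0.156 without hESC replicate 2. Without any 1 of the H3K4me2 libraries of hESC or hDE the smallest p that the permutations allow was 0.1.

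Mesendoderm and endoderm regulators took on H3K27ac in hDE. EOMES, GSC, MIXL1 and LHX1 are transcription factors of the primitive streak, GATA6, FOXA2 and SOX17 specify endoderm, CER1, LEFTY1 and LEFTY2 are secreted Nodal antagonists, and CXCR4 is the surface receptor used to sort definitive endoderm. From hESC to hDE, 1347 genes gained and 237 lost H3K27ac, against 30 to 120 in the mixed splits, in which each side holds 1 library of each stage. The gained count was 2111 without hESC replicate 2, and the lost count was 630 and 497 without hESC replicates 1 and 2 and 362 without hDE replicate 2. Of 20 definitive endoderm genes that could gain the mark, 17 did (85.0% against 14.4% of other genes, two-sided Fisher's exact test, adjusted p = 5.64e-10 over 270 list tests). Primitive streak genes followed with 8 of 12 (66.7% against 14.5%, exact adjusted p = 0.00136). EOMES, GSC, MIXL1 and LHX1 stand in both lists, so these calls, here and below, are not separate results. Both calls held under each setting run for the lists, which were equal list lengths, a 2.5 kb window, the gene end with H3K4me2, the whole gene, a background without genes marked in some libraries, and each library left out. Among the genes of these lists the mark was gained at CER1 (fold enrichment 19.1 and 19.8 in replicates 1 and 2, chromosome 9 from 14718713 to 14722706 in replicate 1), EOMES (19.0 and 21.3, chromosome 3 from 27714407 to 27715651), GSC (16.3 and 22.4) and GATA6 (17.5 and 18.2). FOXA2 had 16.0 and 14.9, SOX17 13.9 and 18.4 and CXCR4 10.6 and 16.0. Signalling feedback genes were called as gained only with equal lengths (exact adjusted p = 0.0393), over whole genes (0.000280), without genes marked in some libraries (0.0474) and without hDE replicate 1 (0.0417). Retinoic acid genes were called only with a 2.5 kb window (7 of 13, 0.0272), and HOX genes gained less often (1 of 39) only without hESC replicate 1 (0.0499), hESC replicate 2 (0.0317) or hDE replicate 1 (0.0242). LHX1 (9.90 and 14.2), FGF8 (11 and 17.3), MIXL1 (9.09 and 10.7) and HHEX (12.7 and 16.6) gained it as well, as did the retinoic acid hydroxylase gene CYP26A1 (18.5 and 14.4).

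Outside the fixed lists the best-ranked hDE gains were at TNFSF14 (17.9 and 19.7), CCDC81, ZAP70, EPSTI1, SHISAL2B, CFAP65, LY6S, MACROH2A1 and GLIS3 (15.1 and 15.5). GLIS3 encodes a zinc finger factor of pancreas and thyroid. Losses in the same step included the pluripotency genes SOX2 (10.7 and 10.4 in the hESC libraries), FOXD3 (8.39 and 7.19) and POU5F1 (8.91 and 6.11). The pluripotency list was called as lost only with equal lengths (4 of 18, exact adjusted p = 0.0393) and without hDE replicate 1 (0.0246), where neural crest genes were called as well (2 of 3, 0.0275). FGF2 (8.25 and 10.6), the growth factor that sustains human stem cells, SFRP2 (11 and 6.91), APELA (6.42 and 5.82) and the claudin gene CLDN4 (4.28 and 5.03) also lost it.

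**Figure D1:**
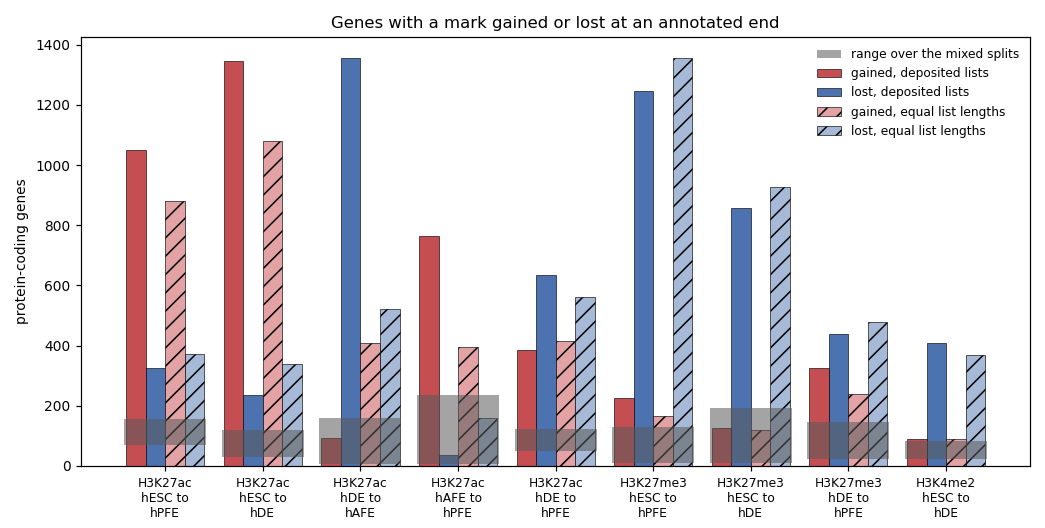
Protein-coding genes gained (red) and lost (blue) on the vertical axis, per mark and contrast on the horizontal axis, with the deposited lists as filled bars, lists of equal length as hatched bars and the range over both mixed splits as grey bands. H3K27ac losses from hDE to hAFE fall from 1356 to 520 and gains rise from 92 to 410 when lists have equal length.

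In anterior foregut endoderm H3K27ac was lost from the primitive streak genes marked in hDE and from most of the definitive endoderm genes marked there, while FOXA2 kept it and a small set of genes took it on. SOX2 marks the anterior foregut, ISL1 and NKX2-3 are homeodomain factors of pharyngeal endoderm, and PTCH1 and ID4 are targets of Hedgehog and BMP signalling. From hDE to hAFE 92 genes gained and 1356 lost the mark (5 to 158 in the mixed splits, a range that contains the 92 gains). With lists of equal length 410 were gained and 520 lost, so gains were 44.1% of the changes in place of 6.35%. Without hAFE replicate 1 the losses were 4075, without hAFE replicate 2 the gains were 329, without hDE replicate 1 the losses were 2035, and without hDE replicate 2 the gains were 147. The hAFE H3K27ac lists are the shortest of the mark, with 42100 and 24871 peaks.

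All 9 of the primitive streak genes that were marked in hDE lost H3K27ac (12.5% of other genes, exact adjusted p = 3.34e-07), and 13 of 21 definitive endoderm genes did (61.9% against 12.4%, exact adjusted p = 5.25e-06). Both calls held under each setting run for the lists. Those lost included EOMES, GSC, LHX1, FGF8, MIXL1, SP5, CER1, GATA6, SOX17 and HHEX. Pluripotency genes lost it in 8 of 17 cases (47.1% against 12.5%, exact adjusted p = 0.00656), with L1TD1 (16.3 and 22 in hDE) and NANOG (4.51 and 7.60) among them. That call ended with lists of equal length (0.0529) and without hAFE replicate 1 (0.488). Liver, pancreas and intestine genes lost it in 4 of 6 cases (exact adjusted p = 0.0276), namely APOA1, MNX1, ALB and HOXD13. The losses at MNX1, ALB and HOXD13 were absent with peaks of −log10 p of 5 or more and of −log10 q of 2 or more. With equal lengths 0 of 1 such gene was lost, which turned the direction, and without hAFE replicate 1 the adjusted p was 0.158. Signalling feedback genes lost it in 7 of 22 cases, with an adjusted p of 0.0876 over all 270 tests and 0.0443 over the 15 lists of that contrast and direction alone. It was called with equal lengths (exact adjusted p = 0.0327), at the end with H3K4me2 (0.0284) and over whole genes (0.0150). Lung, oesophagus and stomach genes were called as lost only with equal lengths (3 of 5, exact adjusted p = 0.0286). Outside the lists the strongest losses were at TNFSF14, ZIC2 (17.8 and 20.3), IFITM1 (17.2 and 15.4), ZAP70, CAVIN3, SHISAL2B, CCKBR, FAM124A, FGF17 (12.2 and 17.3) and DMTN.

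Gains in hAFE were few but included pharyngeal genes in 3 of 25 cases (12.0% against 1.13%, exact adjusted p = 0.0276). These were SOX2 (11 and 8.27 in the hAFE libraries), ISL1 (6.59 and 3.89) and NKX2-3 (5.63 and 3.70). The call ended with equal lengths (0.335) and without hDE replicate 2 (0.0770). Signalling feedback genes gained in 2 of 6 cases, ID4 (10.4 and 3.69) and PTCH1 (5.06 and 5.35), with an exact adjusted p of 0.0203 that ended over whole genes (0.161) and without hAFE replicate 2 (0.118). Without hAFE replicate 2, gains were also called for lung, oesophagus and stomach (3 of 8, exact adjusted p = 0.0279), epithelium (3 of 7, 0.0213) and retinoic acid genes (4 of 10, 0.00628). CLDN4 regained the mark (12.2 and 4.30), and CYP26C1, a retinoic acid hydroxylase gene, gained it (3.55 and 3.91). The gains at ID4 and CYP26C1 were absent with peaks of −log10 p of 5 or more or −log10 q of 2 or more, and that at CYP26C1 also with equal lengths and at the end with H3K4me2. Outside the lists gains fell at the protease gene TMPRSS13, the keratin gene KRT39 (8.58 and 6.24), RBBP8NL, the laminin receptor gene BCAM (7.89 and 4.60), CPA5, RBMS3, the heparan sulfatase gene SULF1 (7.01 and 4.75), WFDC8, PCDH18 and PAICS.

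From hAFE to hPFE the genes gained included the Hedgehog ligand SHH, the thyroid and pharyngeal factor FOXE1, the BMP antagonist NOG and the epithelial factor GRHL3. There were 764 gains and 37 losses (8 to 236 in the mixed splits, a range that contains the losses). With lists of equal length 395 genes gained and 159 lost it, so gains were 71.3% in place of 95.4%. Without hAFE replicate 1 the counts were 3339 and 56, and without hAFE replicate 2 the losses were 199. Without hPFE replicate 1 they were 1596 and 120, and without hPFE replicate 2 1323 and 97. With the deposited lists none of the 15 gene lists was called in this step. The signalling feedback list came nearest with 4 of 12 genes gained (33.3% against 7.67%, exact adjusted p = 0.0795), and its gain was called at the end with H3K4me2 (0.0144), over whole genes (0.0199), without genes marked in some libraries (0.0408) and without hPFE replicate 1 (0.0112). Housekeeping gains were called with equal lengths (2 of 3 genes, exact adjusted p = 0.0346) and without hAFE replicate 1 (0.0404), where neural (0 of 25, 0.0110) and neural crest genes (0 of 22, 0.0250) gained it less often. Pharyngeal genes were called as lost without hPFE replicate 1 (0.00913) and as gained without hPFE replicate 2 (0.0251). SHH had fold enrichments of 8.77 and 4.68 in hPFE, FOXE1 12.1 and 3.94 (chromosome 9 from 97852287 to 97853933 in replicate 1), HOXA2 9.36 and 2.71, GRHL3 7.46 and 5.11, HEY1 6.29 and 5.62, ETV4 5.44 and 4.67 and NOG 6.69 and 3.72. Outside the lists PMEPA1 (7.24 and 9.84), a feedback inhibitor of TGF-beta signalling, DISP3 (7.09 and 24.0), LRRC8E, MRPL4, SLC12A4, ACP3 and BTN3A1 gained it. The losses included FGF10 (4.41 and 4.31 in hAFE), a growth factor of lung and thyroid budding, GPC3 (6.41 and 4.57), IRX3 (4.11 and 3.47) and the ciliogenesis factor FOXJ1 (3.88 and 3.67). The gain at HOXA2 and the loss at IRX3 were absent with peaks of −log10 p of 5 or more or −log10 q of 2 or more, the gain at HOXA2 also with equal lengths, a 200 bp overlap and at the end with H3K4me2, and that at NOG with equal lengths and a 200 bp overlap.

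Over the whole course, from stem cells to pharyngeal foregut endoderm, pharyngeal genes gained H3K27ac and some pluripotency genes, POU5F1 among them, lost it, while SOX2 carried it in hESC and hPFE. MEIS1 and MEIS2 are cofactors of HOX proteins, HOXA2 and HOXB2 are anterior HOX genes, ISL1, NKX2-5 and NKX2-6 are homeodomain factors of the pharynx and heart field, and FOXA1 and FOXA2 are pioneer factors of endoderm. From hESC to hPFE 1051 genes gained and 327 lost the mark (71 to 157 in the mixed splits), so 76.3% of the changes were gains. A simulation called 155 gains and 183 losses where none was planted. Its error rates were set above those of these libraries, so these counts cannot measure how far the losses stand above errors. The losses, fewer than the gains, lie nearer to the mixed splits. Without hESC replicate 2 the counts were 1715 and 603, and without hPFE replicate 1 1751 and 531. Losses were 733 without hESC replicate 1 and 494 without hPFE replicate 2. Pharyngeal genes gained in 12 of 34 cases (35.3% against 11.3%, exact adjusted p = 0.00378 over 270 tests, 0.00336 over the 15 lists of the contrast and direction alone). Without hESC replicate 2 that adjusted p was 0.0580. They included MEIS2 (16.5 and 7.41), MEIS1 (11.1 and 5.78), ISL1 (7.15 and 5.80), SHH (8.77 and 4.68, chromosome 7 from 155809977 to 155812532 in replicate 1), NKX2-6 (6.19 and 4.64) and HOXB2 (8.90 and 3.97). With peaks of −log10 p of 5 or more the gains at FOXA2, HOXA2 and NKX2-5 were absent, and those at FOXA2 and HOXA2 also with −log10 q of 2 or more, equal lengths and a 200 bp overlap.

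Retinoic acid genes gained in 6 of 13 cases (46.2% against 11.3%, exact adjusted p = 0.0196), with TSHZ1 (6.59 and 3.59), CYP26A1 (3.88 and 2.03), CRABP1 (3.82 and 1.96) and both MEIS genes among them. CYP26A1 and CRABP1 were no longer gained with peaks of −log10 p of 5 or more. That call ended with equal lengths (0.149), with only the gene end that carries H3K4me2 (0.0683), over whole genes (0.128), without hESC replicate 1 (0.0822) and without hPFE replicate 1 (0.124). Signalling feedback genes gained in 6 of 15 cases (40.0% against 11.3%, exact adjusted p = 0.0355), namely ID4 (8.65 and 7.31), PTCH1 (8.28 and 7.98), HEY1 (6.29 and 5.62), NOG (6.69 and 3.72), DKK1 (3.61 and 2.81) and LEF1 (2.88 and 1.96). DKK1 and LEF1 were no longer gained with peaks of −log10 p of 5 or more or −log10 q of 2 or more, and LEF1 also not with equal lengths, a 500 bp window, a 200 bp overlap or over whole genes. The list call ended with equal lengths (0.0709), a 2.5 kb window (0.142), without hESC replicate 1 (0.0906) and without hPFE replicate 2 (0.0531). Other list genes gained were FOXA1 (9.37 and 8.83), FOXP2 (10.5 and 8.29), CEBPA, FOXC1 (7.87 and 5.14), TBX3, GRHL1 (4.09 and 4.54) and CLDN3. No call was made for definitive endoderm (5 of 20 gained, exact adjusted p = 0.288), epithelium (3 of 8, 0.253, but 0.0325 over whole genes and 0.0376 without hPFE replicate 2), mesoderm, heart, blood and endothelium (4 of 23, 0.702), neural (0 of 25, 0.339) or the HOX clusters (3 of 39, adjusted p = 1). The same held for thymus, parathyroid and thyroid (2 of 20), lung, oesophagus and stomach (1 of 10), liver, pancreas and intestine (2 of 23), neural crest and mesenchyme (1 of 16), primitive streak (0 of 12) and housekeeping (0 of 1).

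Outside the lists, the best-ranked gains in hPFE were the epithelial adhesion gene MPZL2 (14.7 and 17.6), ZNF436 (17.2 and 13.1), FAM110A, the Notch pathway gene HES4 (10.2 and 17.1), ZNF433, IER5L, RND3 (10.9 and 9.13), the Notch coactivator gene MAML3, the 5-methylcytosine oxidase gene TET2 (9.25 and 9.04) and PRTG. Pluripotency genes lost the mark in 7 of 18 cases (38.9% against 3.73%, exact adjusted p = 6.64e-05), a call that held under each setting run for the lists. Among them were DPPA4 (11.2 and 6.33 in hESC), FOXD3 (8.39 and 7.19), ZFP42 (7.43 and 7.35), POU5F1 (8.91 and 6.11, chromosome 6 from 31168436 to 31170598 in replicate 1), PRDM14 (4.30 and 4.65) and GDF3 (3.92 and 4.20). Neural crest genes were called as lost only at the end with H3K4me2 (2 of 3, exact adjusted p = 0.0321) and over whole genes (2 of 4, 0.0479). Outside the lists losses included FOXH1 (6.57 and 8.94), the transcription factor that carries Nodal signals, SFRP2 (11 and 6.91), ACSM6, NSD1, CYP2S1, NADK, MFSD2B, PIPOX and PTPRZ1.

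**Figure D2:**
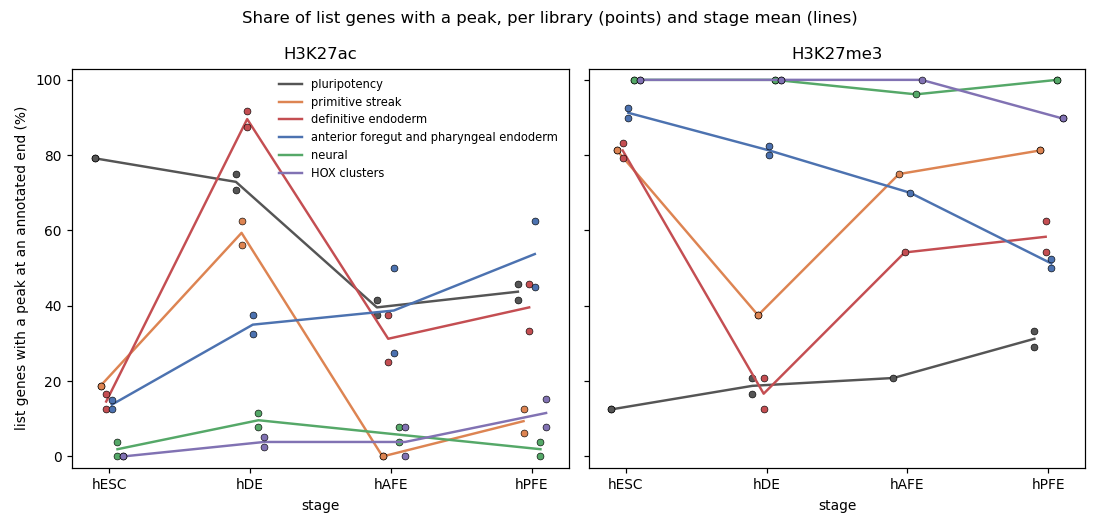
Percent of the genes of 6 fixed lists with a peak at a gene end (vertical axis) at each stage (horizontal axis), for H3K27ac and H3K27me3, with a point per library and a line through the stage means. H3K27ac lies on 21 of 24 definitive endoderm genes in hDE and 7 in hPFE in every library of the stage, and H3K27me3 on 36 of 40 pharyngeal genes in hESC and 19 in hPFE.

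From definitive endoderm to the pharyngeal stage, H3K27ac was gained at pharyngeal genes and lost at primitive streak and definitive endoderm genes more often than at other genes. CCND1 is a G1 cyclin, EFNB2 an ephrin of boundary formation and GRHL3, GRHL1 and CLDN4 belong to surface epithelia. From hDE to hPFE 384 genes gained and 635 lost the mark (48 to 122 in the mixed splits). Without hPFE replicate 1 the counts were 896 and 1039, and without hPFE replicate 2 730 and 1053. Gains were 592 without hDE replicate 2 and losses 1114 without hDE replicate 1. Pharyngeal genes gained in 9 of 25 cases (36% against 4.76%, exact adjusted p = 4.77e-05), a call kept under each setting run for the lists, with SOX2 (7.45 and 3.95), ISL1, NKX2-6, HOXB2, FOXE1, TSHZ1, NKX2-5 and HOXA2 among them. Of these NKX2-5 and HOXA2 were not gained with peaks of −log10 p of 5 or more. Signalling feedback genes gained in 4 of 6 cases (exact adjusted p = 0.00159, 0.0561 over whole genes), namely ID4, PTCH1, NOG and LEF1, the last again absent with the stricter peak thresholds. Epithelium genes gained in 3 of 7 (exact adjusted p = 0.0291), namely CLDN4 (13.5 and 16.6), GRHL3 and GRHL1, which ended with a 2.5 kb window (0.0696) and over whole genes (0.193). Retinoic acid genes gained in 3 of 10 cases, with an exact adjusted p of 0.0795 over all tests, 0.0397 over the 15 lists alone and 0.0123 without hPFE replicate 2. Outside the lists CPA5, CCND1 (12.2 and 9.43), RBMS3, ASXL3, BTN3A1, EFNB2 (8.74 and 6.56), BCAM (11.1 and 5.87) and KRT39 (9.51 and 4.96) gained it.

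Losses from hDE to hPFE took in 8 of 9 primitive streak genes (88.9% against 5.80%, exact adjusted p = 7.75e-08) and 11 of 21 definitive endoderm genes (52.4% against 5.78%, exact adjusted p = 2.89e-07), and both calls held under each setting run for the lists. EOMES, GSC, SOX17, LEFTY1, HHEX and LHX1 were the best-ranked of the endoderm list. Pluripotency genes lost it in 6 of 17 cases (35.3%, exact adjusted p = 0.00401), with LEFTY1, GDF3, NODAL, DPPA4 and PRDM14 among them, PRDM14 not with peaks of −log10 p of 5 or more. Liver, pancreas and intestine genes lost it in 4 of 6 cases (exact adjusted p = 0.00288, 0.0984 with equal lengths), again APOA1, MNX1, ALB and HOXD13, of which APOA1 alone was still lost with peaks of −log10 p of 5 or more. HOX genes were called as lost only without hDE replicate 2 (2 of 2, exact adjusted p = 0.0461). Pharyngeal genes lost it in 4 of 13 cases (30.8% against 5.84%, exact adjusted p = 0.0435), with HHEX, FGF8 and IRX3 (6.23 and 8.29) among them. That call ended with equal lengths (0.137), a 2.5 kb window (0.236), without hDE replicates 1 (0.217) and 2 (0.0846) and without hPFE replicate 2 (0.138).

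Over the whole course more genes lost than gained H3K27me3, and PAX9, ISL1, SHH, HOXA2 and HOXB2 were among the losses. PAX9 encodes a paired box factor needed for pharyngeal pouch derivatives, NR2F2 an orphan receptor induced by retinoic acid, PRDM14 a factor of the pluripotent state, and ZIC2 and ZIC5 zinc finger factors active in early neural cells. From hESC to hPFE 227 genes gained and 1246 lost H3K27me3 (11 to 130 in the mixed splits). Over whole genes 1165 were gained and 925 lost, which turned the direction, with gains at 55.7% of the changes in place of 15.4%. Losses were 2279 without hESC replicate 1, and gains were 374 without hESC replicate 2, 796 without hPFE replicate 1 and 689 without hPFE replicate 2. With replicate 2 of each stage alone 833 were gained and 2443 lost. Pharyngeal genes lost it in 14 of 36 cases (38.9% against 32.3%, exact adjusted p = 0.914), which was no call. Among their hESC peaks that were gone in hPFE were those at PAX9 (17.8 and 28.1 in hESC, chromosome 14 from 36644502 to 36661597 in replicate 1), ISL1 (14.0 and 21.2), SHH (11.8 and 23.4) and HOXB2 (8.40 and 17.6). HOXA2 had 11.3 and 17, and HOXB1 12.4 and 20.8. FOXA1 (16.3 and 23.1), FOXC1 (13.5 and 23.7), MEIS1 (11.5 and 11.3), MEIS2 (9.89 and 10.5), HEY1 (10.5 and 17.6), PTCH1 (5.89 and 12.0), FOXP2, GRHL1, GRHL3 and SOX9 lost it too. Outside the lists the losses were led by TTC6, YAF2, SAMD11, ZNF503 (12.8 and 25.9), NR2F2 (13.5 and 19.4), PRTG, KAZALD1, KIF26B and the guidance cue gene SLIT2 (13.3 and 19.6).

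Neural, neural crest, HOX, and liver, pancreas and intestine genes lost H3K27me3 from hESC to hPFE less often than other genes. Losses were 0 of 26 neural genes (32.6% of other genes, exact adjusted p = 0.00136), 0 of 21 neural crest genes (0.00656), 0 of 17 liver, pancreas and intestine genes (0.0264) and 4 of 39 HOX genes (10.3%, 0.0196). HOXA2, HOXB1 and HOXB2 were among the HOX genes that lost it. Over whole genes none of these calls held (0.0714, 0.200, 0.254 and 0.775). The list tests did not take the rank of the hESC peaks into account. Among genes with H3K27me3 and no H3K27ac in hESC, losses went from 5.75% in the strongest to 51.7% in the weakest quintile of rank. Strong hESC peaks at the genes of these lists were therefore not excluded as a reason for few losses. The liver, pancreas and intestine call ended with equal lengths (0.197), with a 2.5 kb window (0.0528) and without hPFE replicate 1 (0.0736), and the HOX call with a 2.5 kb window (0.0696) and with only the gene end that carries H3K4me2 (0.0986). Mesoderm, heart, blood and endothelium genes (2 of 18 lost, exact adjusted p = 0.296) and lung, oesophagus and stomach genes (3 of 10, exact adjusted p = 1) were not called. Primitive streak genes and thymus, parathyroid and thyroid genes, each with 0 of 13 lost, had an exact adjusted p of 0.0876 over 270 tests and 0.0311 over the 15 lists of the contrast and direction alone. Both lists were called with equal lengths (exact adjusted p = 0.0410 and 0.0286), at the end with H3K4me2 (0.0468 for each), without genes marked in some libraries (0.0259 and 0.0408) and without hESC replicate 1 (0.00904 and 0.0247) or 2 (0.0470 for each), and the primitive streak list also without hPFE replicate 2 (0.0143). Signalling feedback genes were called as lost more often with a 2.5 kb window (12 of 20, 0.0482) and over whole genes (12 of 21, 0.000957). Pluripotency genes gained H3K27me3 in 4 of 21 cases (19.0% against 1.53%, exact adjusted p = 0.00401), with PRDM14 (6.91 and 7.64), L1TD1 (3.73 and 3.78) and USP44 (2.82 and 3.02) among them, USP44 only without the stricter peak thresholds. The call ended with a 2.5 kb window (0.127) and without hPFE replicate 1 (0.140). Outside the lists GPR176 (7.70 and 12.4), ZIC5 (6.77 and 7.38), ZIC2 (5.82 and 5.97) and the serotonin receptor gene HTR7 gained it.

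In the step from hESC to hDE, H3K27me3 came off the endoderm regulators themselves. Losses numbered 856 and gains 127 (10 to 194 in the mixed splits, a range that contains the gains). Losses were 1891 without hESC replicate 1 and 1343 without hDE replicate 2, and gains were 247 without hESC replicate 2, 721 without hDE replicate 1 and 218 without hDE replicate 2. Over whole genes 269 were gained and 694 lost, and with replicate 2 of each stage alone 759 and 1988. Definitive endoderm genes lost it in 14 of 19 cases (73.7% against 22%, exact adjusted p = 6.64e-05), which held under each setting run for the lists, with LHX1 (16.8 and 26.4 in hESC), EOMES (15.3 and 22.6), GATA6 (15.8 and 23.2), GATA4 (10.7 and 20.4), SOX17 (10.1 and 15.9) and GSC (12.3 and 20.2) at the head. Signalling feedback genes lost it in 9 of 16 cases (56.2% against 22.1%, exact adjusted p = 0.0276), among them SP5 (15.3 and 24.8), DKK1 (10.1 and 15.7) and CER1. That call ended with a 2.5 kb window (0.310), without hESC replicate 1 (0.141) and without hDE replicate 2 (0.166). CYP26A1 (10.2 and 22.6), HHEX (8.30 and 15.4) and the growth factor gene FGF17 (16.3 and 22.9) lost it as well. Neural genes (0 of 26, exact adjusted p = 0.0276) and HOX genes (0 of 39, 0.00219) lost it less often than other genes. The neural call ended with a 2.5 kb window (0.0807), the end with H3K4me2 (0.104) and whole genes (0.203), and the HOX call over whole genes (0.0626). Called only in part of the settings were fewer losses at liver, pancreas and intestine genes (0 of 17, exact adjusted p = 0.00624 without hESC replicate 1 and 0.0150 without hDE replicate 2), pharyngeal genes (5 of 37, 0.0247 without hESC replicate 1) and mesoderm genes (1 of 18, 0.0450 without hDE replicate 2). The same applied to gains at pharyngeal genes (2 of 4, exact adjusted p = 0.00454 with equal lengths and 0.0140 without hESC replicate 2), pluripotency genes (3 of 22, 0.00664 at the end with H3K4me2) and signalling feedback genes (4 of 13, 0.0244 without hDE replicate 1). SOX2 was among the gains (3.55 and 4.23 in hDE), as were PRDM14 (3.28 and 6.87) and GLI1 (2.86 and 3.92), the last absent with peaks of −log10 p of 5 or more.

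From hDE to hPFE H3K27me3 returned to endoderm and primitive streak regulators and left pharyngeal ones. There were 325 gains and 439 losses (22 to 147 in the mixed splits). The larger side depended on the setting: without hPFE replicate 1 there were 995 gains and 495 losses, without hPFE replicate 2 825 and 659, over whole genes 989 and 386, and with a peak in any library 1495 and 1437. Losses were 1314 without hDE replicate 1, gains 544 without hDE replicate 2, and with replicate 2 alone 1048 were gained and 1429 lost. Definitive endoderm genes regained the mark in 10 of 19 cases (52.6% against 1.99%, exact adjusted p = 2.43e-10) and primitive streak genes in 7 of 10 (70.0% against 2.01%, exact adjusted p = 1.47e-08), both under each setting run for the lists. EOMES (8.43 and 9.48 in hPFE), GSC (7.18 and 12.9), SOX17 (9.36 and 8.37), LHX1 (8.22 and 9.22), HHEX (6.56 and 9.77), GATA4 (5.89 and 8.43) and SP5 (8.47 and 10.7) were among them. Pluripotency genes gained it in 4 of 19 cases (exact adjusted p = 0.00656, ending with a 2.5 kb window at 0.153 and without hPFE replicate 1 at 0.149). Pharyngeal genes gained it in 3 of 7 (HHEX, FGF8 and OTX2, exact adjusted p = 0.00401, ending at 0.357 with a 2.5 kb window, 0.128 over whole genes and 0.0584 without hPFE replicate 1). They lost it in 13 of 32 cases (40.6% against 16.0%, exact adjusted p = 0.00992), with HOXA2, PAX9 (8.24 and 9.58 in hDE), HOXB2, SHH (7.65 and 8.54) and ISL1 (6.21 and 9.29) among them. The loss call ended with a 2.5 kb window (0.261), over whole genes (0.194) and without hDE replicate 1 (0.569). Fewer losses were called for neural genes (0 of 26) with equal lengths (exact adjusted p = 0.0410), without hDE replicate 1 (0.00117) or 2 (0.0423) and without hPFE replicate 2 (0.0120), and for neural crest (0.0158) and HOX genes (0.0175) without hDE replicate 1.

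Genes that lost 1 mark between hESC and hPFE often gained the other. The marks rarely share a gene end, so a low share was given beforehand where the first mark was kept, and the ratios below measure that exclusion as well as any exchange. Genes with a peak in only some of the hPFE libraries are counted below among those that kept the mark. Of the genes that lost H3K27me3 and had no H3K27ac in hESC, 285 of 679 gained H3K27ac (42%, exact binomial 95% interval 38.2 to 45.8), against 120 of 2105 that kept H3K27me3 (5.70%, odds ratio 12.0, two-sided Fisher's exact test, adjusted p = 2.79e-102 over 5 tests). Without hPFE H3K27ac replicate 1 the odds ratio was 7.59. In the other direction 58 of 232 genes that lost H3K27ac gained H3K27me3 (25%, 19.6 to 31.1), against 38 of 7271 that kept it (0.523%, odds ratio 63.4, Fisher's exact adjusted p = 7.71e-65). That ratio was 19.1 and 15.6 without hPFE H3K27me3 replicates 1 and 2, 32.1 and 35.6 without hESC H3K27ac replicates 1 and 2, and 41.6 without hPFE H3K27ac replicate 1. It was 14.3 with a 2.5 kb window and 2.88 over whole genes, where the first ratio was 5.17. With peaks of −log10 p of 5 or more it was 118, at the gene end with H3K4me2 153, and without genes marked in some libraries 116, where the first ratio was 29.5. MEIS1, MEIS2, SHH, ISL1, HOXA2, HOXB2, FOXA1, PTCH1 and HEY1 went from H3K27me3 to H3K27ac, and PRDM14 went the other way. In hDE, between these stages, MEIS1, MEIS2, HEY1 and PRDM14 carried both marks, not necessarily at the same gene end. HOXA2 gained H3K27ac only without the stricter peak thresholds.

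Bivalent genes, those with both H3K4me2 and H3K27me3 in hESC, numbered 3710, against 76 with H3K27me3 and no H3K4me2, 9543 with H3K4me2 and no H3K27me3 and 4468 with neither. Each mark could lie at either annotated end, so a bivalent gene here need not carry both marks at the same promoter. H3K27ac was gained by hPFE at 402 of 2649 bivalent genes (15.2%, 13.8 to 16.6), at 381 of 1022 with H3K4me2 alone (37.3%, 34.3 to 40.3) and at 100 of 4210 with neither (2.38%). Only genes without H3K27ac in hESC could gain it, 2649 of the 3710 bivalent genes but 1022 of the 9543 with H3K4me2 alone. The latter are thus a small remainder of their class, a selection that the comparison did not take into account. Bivalent genes gained it less often than those with H3K4me2 alone (odds ratio 0.301, Fisher's exact adjusted p = 3.35e-45) and more often than those with neither (7.35, Fisher's exact adjusted p = 2.63e-86). The latter ratio was 3.65 without hPFE H3K27ac replicate 1 and 15.1 with lists of equal length. H3K27me3 was lost at 1191 of 3710 bivalent genes (32.1%, 30.6 to 33.6) and at 36 of the 76 without H3K4me2 (47.4%, 35.8 to 59.2, odds ratio 0.525, exact adjusted p = 0.00627). That difference ended with peaks of −log10 p of 5 or more (0.132) and without hESC H3K4me2 replicate 2 (0.0554), and without hESC H3K27me3 replicate 1 the odds ratio was 0.322. The comparison did not take the rank of the hESC H3K27me3 peaks into account.

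SOX17 carried H3K27ac in both hDE libraries and at no other stage, and H3K27me3 in both hESC, the hAFE and both hPFE libraries (chromosome 8 from 54457935 to 54460892). FOXA2 carried H3K27ac in every library from hDE on and H3K27me3 in all 7 libraries of that mark. POU5F1 carried H3K27ac in hESC, and its H3K4me2 was present in hESC and hDE. NANOG carried H3K27ac in hESC (8.40 and 8.75), hDE (4.51 and 7.60) and hPFE (3.21 and 1.99), with no peak in hAFE. Its gain from hAFE to hPFE was absent with peaks of −log10 p of 5 or more or −log10 q of 2 or more, equal lengths, a 500 bp window, a 200 bp overlap and at the end with H3K4me2. SOX2 carried H3K27ac in every library of hESC, hAFE and hPFE, and in hDE H3K27me3 in its place. The pouch regulators PAX9, PAX1 and HOXA3 had an H3K27ac peak in hPFE replicate 1 (7.06, 8.84 and 8.67) and none in hPFE replicate 2. PAX9 had lost H3K27me3 in both hPFE libraries, while PAX1 kept it (2.67 and 3.11), as did HOXA3 (10.1 and 11). TBX1, a regulator of the pharyngeal arches and pouches, had H3K27me3 in all 7 libraries and H3K27ac in none of the 8. EYA1, a transcriptional coactivator of pharyngeal pouches, had H3K27me3 in hESC alone, with a loss to hDE that was absent with peaks of −log10 p of 5 or more, and H3K27ac in hDE replicate 2 (2.94) and hPFE replicate 2 (2.36).

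**Figure D3:**
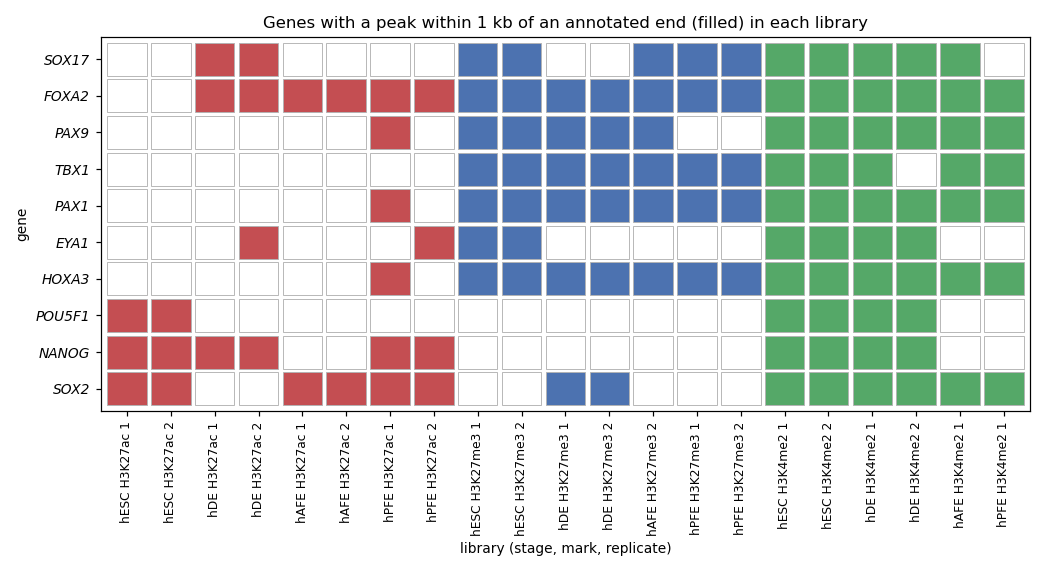
Peaks within 1 kb of a gene end for genes named beforehand (vertical axis) in each of the 21 libraries (horizontal axis, by mark, stage and replicate), with a filled cell for a peak. SOX17 has H3K27ac in the 2 hDE libraries, and PAX9, PAX1 and HOXA3 have it in 1 hPFE library each.

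Away from gene ends, H3K27ac regions near endoderm genes appeared in hDE and regions near pharyngeal, retinoic acid and signalling genes in hPFE. From hESC to hDE 25564 distal regions gained and 7236 lost H3K27ac (440 to 885 in the mixed splits), from hDE to hPFE 8941 and 24652 (578 to 1545), and from hESC to hPFE 10048 and 8156 (493 to 1462). From hDE to hAFE 2692 were gained and 27222 lost (133 to 618), and from hAFE to hPFE 7982 and 1572 (144 to 1353). With lists of equal length gains were 33.6% in place of 9.0% from hDE to hAFE (2942 gained, 5825 lost), and 39.6% in place of 83.5% from hAFE to hPFE (1252 and 1910), which turned the direction. From hESC to hPFE equal lengths gave 6918 and 8274, which turned it as well. Of all 263882 distal regions 67.9% lay within an annotated gene. Without 1 library the counts moved by construction, since a region then needs a peak in 1 library of that stage. Gains were 68598 and 40409 from hESC, 65447 and 38627 from hDE and 67479 and 38149 from hAFE without hPFE replicates 1 and 2, and 60746 and 53170 from hESC to hDE without hDE replicates 1 and 2. Losses without hESC replicates 1 and 2 were 34836 and 41395 to hPFE and 33769 and 39917 to hDE, more than the gains of 11089 and 10733, and of 27650 and 26757. Without hDE replicates 1 and 2 losses were 63470 and 55766 to hAFE and 59045 and 51758 to hPFE. Without hAFE replicates 1 and 2, gains from hDE were 5883 and 10363 and losses to hPFE 4703 and 7073.

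Definitive endoderm genes had a gained distal region nearest to them in hDE in 20 of 24 cases (83.3% against 40.9% of other genes, exact adjusted p = 0.000874 over 150 tests). GATA6 had 20 such regions, LHX1 16, FOXA2 12 and CXCR4 10, and these genes, like those that follow in this paragraph, were chosen after their values were seen. That call ended without hDE replicate 1 (0.320). In all distal list tests a gene with more distal regions nearest to it had more chances to count. The number of regions per gene was not taken into account. From hESC to hPFE gained regions lay near 21 of 37 pharyngeal genes (56.8% against 25%, exact adjusted p = 0.00155), 13 of 22 retinoic acid genes (59.1%, 0.0134) and 20 of 31 signalling feedback genes (64.5%, 0.000303). MEIS1 had 14, MEIS2 8, ISL1 6, PAX1 5 and PAX9 3 of them, and SMAD7 6, PTCH1 5 and ID1 4. From hDE to hPFE the same 3 lists were called (17 of 35, 0.0207, 12 of 22, 0.0265, and 17 of 26, 0.000303). From hDE to hAFE the pharyngeal (12 of 35, 0.000303) and signalling (9 of 26, 0.00209) lists were called, and from hAFE to hPFE the signalling list (18 of 31, 0.000303). Equal lengths ended 3 calls: retinoic acid from hESC (0.316) and from hDE (0.189), and signalling from hAFE (exact adjusted p = 1). Retinoic acid from hDE also ended with a limit of 50 kb (0.0904). All 7 calls that end in hPFE ended without hPFE replicate 1, with adjusted p of 1 for 5 of them, 0.726 for the signalling list from hAFE and 0.822 for that from hDE, and the pharyngeal list from hDE then lay at −1.82 points against other genes. Without hPFE replicate 2 the calls from hESC ended (0.0565 for pharyngeal, 0.211 for retinoic acid and 0.119 for signalling), as did signalling from hAFE (0.0543), and pharyngeal (0.0543) and retinoic acid (0.211) from hDE.

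H3K4me2 lay on distal regions mainly at the stage that carried H3K27ac there. Of the regions gained from hESC to hDE, 6.16% (5.87 to 6.46) had H3K4me2 in hESC, 23.9% (23.4 to 24.5) in hDE, 13.1% in hAFE and 8.29% in hPFE. Each is above the highest of 100 random placements (1.38, 1.03, 2.24 and 2.10%). Of the regions gained from hDE to hPFE, 9.71% had it in hESC, 3.15% (2.80 to 3.54) in hDE, 26.7% in hAFE and 36.8% (35.8 to 37.9) in hPFE, with random placements up to 1.48, 1.03, 2.21 and 2.27%. Regions lost from hESC to hDE had it at 42.5% in hESC and 4.06% in hDE, and regions lost from hDE to hPFE at 22.9% in hDE and 4.95% in hPFE. Shares in hESC and hDE require a peak in both libraries and those in hAFE and hPFE in 1. With replicate 1 of each stage, the shares in hESC and hDE were 10.6 and 36.4% of regions gained in hDE, and the hDE share of those gained in hPFE was 6.10%.

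**Figure D4:**
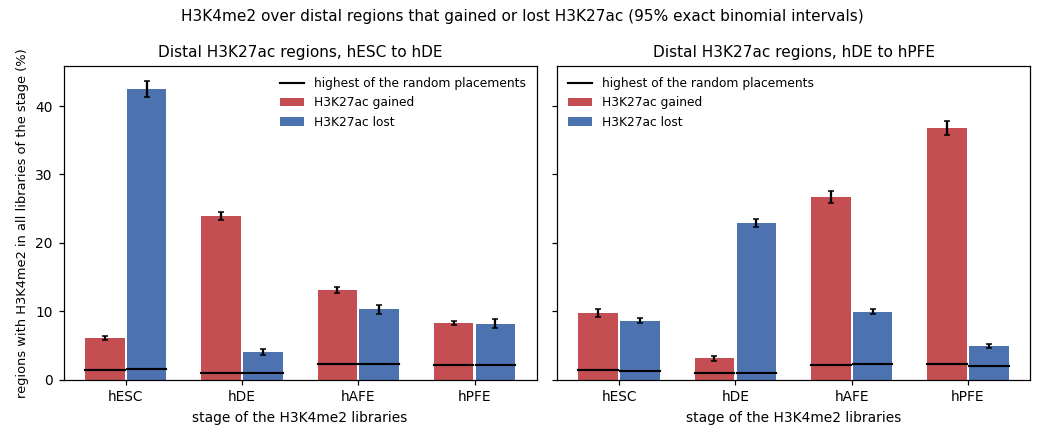
Percent of distal H3K27ac regions that overlap an H3K4me2 peak (vertical axis) at each stage (horizontal axis), for regions gained (red) and lost (blue) in 2 contrasts, with exact binomial 95% intervals as error bars and the highest of 100 random placements as a black line. Regions gained from hDE to hPFE rise from 3.15% in hDE to 36.8% in hPFE.

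At gene ends H3K4me2 changed at few genes from hESC to hDE. MYL7 encodes atrial myosin light chain, ANGPT2 and VWF are endothelial, TBX5 is a heart and limb factor and CDH2 is N-cadherin. There were 90 gains and 408 losses (23 to 82 in the mixed splits), and none of the 15 lists was called with all libraries and a 1 kb window (smallest exact adjusted p = 0.107, HOX clusters, 1 of 1 gained). Gains were called for primitive streak genes with a 2.5 kb window (2 of 2 genes, exact adjusted p = 0.0135), for signalling feedback (0.0295) and HOX genes (0.0195) without hESC replicate 2, and for liver, pancreas and intestine genes without hDE replicate 1 (0.0266). Gains were 260 and 224 without hDE replicates 1 and 2, and losses 678 and 651 without hESC replicates 1 and 2 and 829 without hDE replicate 2. MYL7 (6.08 and 6.26 in hDE), ANGPT2 (6.20 and 5.01), VWF (5.22 and 3.53), IGF2 (4.38 and 4.69) and HOXB8 (3.65 and 5.84) gained it, HOXB8 not with peaks of −log10 p of 5 or more. CDH2 (9.16 and 13.2 in hESC), TBX5 (6.12 and 7.35), TNNT2 (4.74 and 6.37), CDX4 (5.50 and 5.31), CDX1, HOXB1 (4.90 and 9.33), DPPA4 (6.30 and 5.77), GDF3 and CLDN4 (5.25 and 5.11) lost it, GDF3 not with peaks of −log10 p of 5 or more. Where a stage has 1 library the counts have no mixed split beside them: H3K27me3 gave 434 gains and 411 losses from hDE to hAFE and 301 and 499 from hAFE to hPFE, and H3K4me2 433 and 441, and 699 and 717, in the same steps.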

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

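The tests of differing hPFE cultures, of the peak numbers of the hPFE lists and of weak hESC peaks, and the comparisons of hPFE with hAFE by peak area, were chosen only after the results they explain were seen, and the other tests in this part were set down before. In the data outside the main measurement, hESC H3K27me3 replicate 1 had 224 peaks (0.801%) off chromosomes 1 to 22, X and Y, on sequences that no comparison used, against a range of 0.165 to 0.801% for H3K27me3 libraries, 0.0171 to 0.161% for H3K27ac and 0.0217 to 0.0819% for H3K4me2. The other hESC H3K27me3 library had 331 such peaks (0.602%), and no explanation was tested.

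From hDE to hAFE H3K27ac was lost at 1356 genes and gained at 92. With lists of equal length 55.9% of the changes were losses, the result set down beforehand for shorter hAFE lists as the cause. Equal lengths, however, move the counts toward balance whether the hAFE lists are short for technical reasons or from a real loss. The test therefore cannot decide whether list length accounts for the imbalance. A mark present in hAFE but not called could not be told apart from a real loss, since 31.2% of the lost genes (28.7 to 33.7, 423 genes) were marked again in both hPFE libraries and 39.7% (539) were unmarked in both. At equal lengths primitive streak and definitive endoderm genes were still lost more often than other genes. A change of the cells between these stages stays open as the biological explanation and was not tested apart from list length.

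Both hPFE H3K27ac libraries shared less peak area with each other (Jaccard index 0.256) than the libraries of any other stage, and list length is argued against as the whole cause, because at equal lengths the index was 0.361 and that of the lowest other pair 0.394. A library of another stage under the hPFE name could not be told apart from variation within hPFE: by marked genes each hPFE library was nearer to the other than to hDE, the closest other stage as a mean of its libraries, by 0.0307 for replicate 1 and 0.0398 for replicate 2, but by peak area replicate 1 was nearer to hAFE replicate 1 (0.315) than to hPFE replicate 2 (0.256), also at equal lengths (0.392 against 0.361). A hAFE replicate 1 that belongs to another stage stays open too, as its area index was 0.355 with hAFE replicate 2 and 0.315 with hPFE replicate 1 (0.398 and 0.392 at equal lengths), while by marked genes it was nearer to hPFE (0.827 against 0.678), a comparison that the short list of hAFE replicate 2 limits. Cultures that differ in pharyngeal genes cannot be told apart from other variation between the libraries either: 9 pharyngeal list genes carried H3K27ac in replicate 1 alone and 2 in replicate 2 alone, against 877 and 1108 other genes (two-sided Fisher's exact p = 0.0147), but genes seen before the test was chosen were among them. Without the genes named beforehand the counts were 6 and 1 (Fisher's exact p = 0.0491, and 0.0983 adjusted for both tests), and the labels do not say whether the libraries come from separate cultures.

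H3K27me3 was lost at 1246 genes and gained at 227 from hESC to hPFE. By peak number the hPFE lists were not shorter, with 76441 and 66283 peaks against 27958 and 55027 in hESC. Their covered area was 22.9 and 22.2 Mb against 19.5 and 31.8 Mb. Peaks of −log10 p of 5 or more numbered 16013 and 15638 against 14745 and 21915. The hPFE peaks were also narrower, with medians of 176 and 174 bp against 268 and 225 bp. Peak number therefore cannot decide whether the hPFE lists missed more of the mark. Equal lengths, the test set down before, decide nothing here, as they shorten the hPFE lists most. Weak hESC peaks falling under the threshold with the mark unchanged are argued against for the losses that came with H3K27ac. Genes that still carried the mark in full would gain H3K27ac as seldom as those that kept it. Within quintiles of hESC rank the odds of that gain were 11.2 times as high (8.55 to 14.7) where H3K27me3 was lost as where kept. A partial drop of the mark under the threshold and a full loss cannot be told apart by this ratio. It also measures how rarely the marks share a gene end. Genes with a peak in only some of the hPFE libraries count as kept here. Losses were nevertheless more common among weaker peaks, with 5.75% in the strongest and 51.7% in the weakest quintile, so for losses without a gain of H3K27ac a weaker enrichment in hPFE stays open, as does a difference between stages. The hESC libraries come from an earlier deposit, and that batch and the stage cannot be told apart.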

How the results depend on the processing

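The gene end with more H3K4me2, the whole gene, the background without genes marked in some libraries, and, for distal H3K27ac, equal lengths of counts and single libraries left out were chosen only after the data were seen. The other alternatives were chosen before the data were examined. Of the values that answer a comparison, 290 stayed within 1.5 times of the reported count or on the same side of the threshold, 122 moved and 13 fell short of the threshold. Of those for single lists 335 were the same, 53 moved, 69 fell short and 2 turned direction. Unless stated, the cause was not tested.

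Counting a peak in any library as marked, a wider definition by construction, gave 2259 gained and 1009 lost for H3K27ac from hESC to hPFE, 2221 and 890 from hESC to hDE, 345 and 2363 from hDE to hAFE, 2155 and 218 from hAFE to hPFE and 1242 and 1323 from hDE to hPFE. For H3K27me3 it gave 1258 and 2421 from hESC to hPFE, 812 and 2033 to hDE and 1495 and 1437 from hDE to hPFE, which turned the larger side, and for H3K4me2 394 and 921. Peaks of −log10 q of 2 or more gave 147 H3K27ac losses from hESC to hDE, 52 gains from hDE to hAFE and 24 losses from hAFE to hPFE, 151 and 81 H3K27me3 gains from hESC to hPFE and hDE, and 41 H3K4me2 gains. Peaks of −log10 p of 5 or more gave 79 H3K27me3 gains from hESC to hDE and 32 H3K4me2 gains, and the odds ratio of H3K27me3 loss, bivalent against H3K27me3 alone, was 0.656 (exact adjusted p = 0.132).

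Equal lengths gave 410 gained and 520 lost from hDE to hAFE, and 395 and 159 from hAFE to hPFE. They gave 5825 distal losses in the former and 1252 distal gains in the latter step. A window of 500 bp gave 796 H3K27me3 losses from hESC to hPFE and 712 H3K4me2 losses, one of 2.5 kb 380 H3K27me3 gains from hESC to hPFE, and an overlap of 200 bp 59 H3K4me2 gains. Over whole genes there were 1430 gains and 24 losses of H3K27ac from hAFE to hPFE and 1165, 269 and 989 H3K27me3 gains from hESC to hPFE, hESC to hDE and hDE to hPFE. Replicate 2 alone gave 833 and 2443, 759 and 1988, and 1048 and 1429 gained and lost in these 3 contrasts.

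With 1 library left out, a stage rests on its other library and more genes pass by construction. H3K27ac gains and losses ranged from 1505 to 1751 and 494 to 733 from hESC to hPFE, 1633 to 2111 and 287 to 630 from hESC to hDE, 108 to 329 and 1416 to 4075 from hDE to hAFE, 808 to 3339 and 56 to 199 from hAFE to hPFE, and 488 to 896 and 844 to 1114 from hDE to hPFE. H3K27me3 ranged from 247 to 796 and 1349 to 2279 from hESC to hPFE, 140 to 721 and 931 to 1891 from hESC to hDE, and 355 to 995 and 495 to 1314 from hDE to hPFE. H3K4me2 ranged from 113 to 260 and 590 to 829. Distal gains and losses ranged from 10733 to 68598 and 8769 to 41395 from hESC to hPFE, 26757 to 60746 and 7738 to 39917 from hESC to hDE, 2985 to 10363 and 27644 to 63470 from hDE to hAFE, 8226 to 67479 and 2161 to 7073 from hAFE to hPFE, and 9480 to 65447 and 25942 to 59045 from hDE to hPFE.

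The replicate block, which permutes stages only among libraries with the same number, left the similarity differences at 0.181, 0.114 and 0.147 for H3K27ac, H3K27me3 and H3K4me2, with adjusted exact p of 0.0625, 0.0625 and 0.0833. Each raw p was the smallest that so few permutations allow, so the block says nothing about stability. For counts no replicate block is possible, as requiring the change within each pair gives the same count. Equal lengths (0.220, 0.174 and 0.155) and marked gene sets (0.0721, 0.122 and 0.0355) kept each call. Without 1 library the difference was 0.0453 to 0.171 for H3K27me3 and 0.106 to 0.189 for H3K4me2.

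Of the 34 list calls at gene ends, equal lengths kept 26, the 2.5 kb window 23, the end with H3K4me2 31, whole genes 22 and the background without genes marked in some libraries all 34. With single libraries left out 117 of 136 were kept. The calls made numbered 35, 26, 37, 28 and 38 under those settings. The loss of H3K27ac from liver, pancreas and intestine genes between hDE and hAFE turned to −6.89 points against other genes at equal lengths, where 1 such gene was left. Of the 10 distal calls a 50 kb limit kept 9, equal lengths 7 and single libraries left out 26 of 40. The number called was 3 without hPFE replicate 1 and 6 without hPFE replicate 2, within a range of 3 to 12. The distal excess of the pharyngeal list from hDE to hPFE ranged from −1.82 points without hPFE replicate 1, a turned direction, to 26.8 without hDE replicate 2.

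Exchange of marks kept its direction and its call under every alternative run for it. The odds ratio of H3K27me3 loss, bivalent against H3K27me3 alone, ranged from 0.322 to 0.700 with single libraries left out and missed the threshold without hESC H3K4me2 replicate 2 (exact adjusted p = 0.0554). H3K4me2 over distal regions moved with the overlap required. At 25% coverage it was 4.48% in hESC, 14.5% in hDE for regions gained in hDE, and 2.11% in hDE and 28.5% in hPFE for regions gained in hPFE, and with replicate 1 alone 10.6, 36.4 and 6.10% for hESC, hDE and hDE.

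Consensus words, with their narrower window, and the background matched on CpG content were planned and not run, as no genome sequence was at hand. The read depth behind the lists was not analysed here.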

Other observations

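The test of a returning H3K27me3 in this part was chosen only after the result was seen. Followed over hESC, hDE and hPFE, 399 genes carried H3K27ac in hDE alone, 261 in hPFE alone, 636 in hDE and hPFE and 138 in hESC alone. For each mark, genes with a peak in only some libraries of any of these stages were left out. The genes of hPFE alone included list genes such as ISL1, NKX2-5, NKX2-6, HOXA2, HOXB2, FOXE1, GRHL1, GRHL3, ID4, NOG and PTCH1. FOXA1, FOXA2, MEIS1, MEIS2, CYP26A1 and HEY1 carried it in both hDE and hPFE, while SOX2 and CLDN4 were among 51 genes with H3K27ac in hESC and hPFE and none in hDE. These groups leave hAFE out, and HEY1 was unmarked there. H3K27me3 was absent in hDE alone at 127 genes, was lost from hDE on at 629 and after hDE at 333, and stayed throughout at 1870.

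Among single genes with many gained distal H3K27ac regions, chosen after their values were seen, hPFE had PDGFC with 30, CADM1 with 22, HMGA2 with 20, IGF1R with 20 and the epithelial factor gene GRHL2 with 14. In hDE the receptor gene ROR2 had 36, PLXNA2 and PRDM1 28 each, CDH2 27 and BMP2 24. Regions lost from hESC to hPFE lay near CHN1 (21), MYC (15) and DAZL (12), and those gained in hAFE near SULF1 (12), LGR4 (9) and GLI3 (7). Of regions gained from hESC to hDE 61.0% lay within genes, against 72.1% of those gained from hESC to hPFE.

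A hypothesis from these groups is that H3K27me3 may return where a transient H3K27ac leaves. Genes with a peak of either mark in only some libraries of hESC, hDE or hPFE were left out of the comparison below. Among genes that lost H3K27me3 from hESC to hDE and had no H3K27ac in hESC or hPFE, H3K27me3 was present in both hPFE libraries at 45 of 69 with H3K27ac in hDE (65.2%, 52.8 to 76.3) and at 17 of 61 without it (27.9%, 17.1 to 40.8). Within quintiles of the hESC H3K27me3 rank the common odds ratio was 3.68 (1.63 to 8.34). EOMES, GSC, LHX1, MIXL1, SP5, SOX17, HHEX, GATA4, FGF8, WNT3, FGF17, BMP2 and NTN1 are among the 45, named after their values were seen. Where H3K27ac stayed in hPFE the share was 3 of 111, a low value that follows from the marks rarely sharing a gene end and tests nothing.

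The hAFE H3K27ac libraries differ in length, with 10036 marked genes in replicate 1 and 6946 in replicate 2, and replicate 2 had 2130 peaks with a −log10 q of 0. Of 24 housekeeping genes, 18 carried H3K27ac in both hAFE libraries. Differences between replicate 1 and replicate 2 of a stage correlated little with those of other stages. The correlations over genes ranged from −0.0410 to 0.0316 for H3K27ac, from 0.0240 to 0.0629 for H3K27me3 and were 0.0569 for H3K4me2. All H3K27me3 and H3K4me2 values were positive, so a weak pairing by replicate number is not excluded for these marks.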
